A study of Homo sapiens with 4 samples.

How the data were processed

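RNA-seq libraries from DU145 cells were grouped by the genotype in the labels: SPOP-F133V, 2 libraries, and wild-type, 2 libraries. Per the labels' protocols, total RNA was extracted with TRIzol and a column kit, and single reads of 75 bases were sequenced on a NextSeq500 instrument. Whether poly-A RNA was selected, whether the library kit kept strand, and whether strand was used in counting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart.

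The authors deposited raw read counts per gene for each library, which are whole numbers and not normalized. Per the submitters' processing notes, the tools were TopHat2 version 2.0.10 and HTSeq version 0.6.0 and the genome build was hg38; the annotation release is not given in the sources used here. Each table held 60614 gene IDs and the counter's tallies of reads assigned to no gene. The tallies stayed out of library sizes and tests. Of all reads in the tables, those over no gene made up 6.12% and 6.25% in F133V replicates 1 and 2 and 6.53% and 6.52% in the wild-type replicates. Reads with several alignments made up 15.1%, 16.6%, 14.6% and 13.6% in the same order, and reads over more than 1 gene 3.73%, 3.69%, 3.50% and 3.52%. Reads counted in genes ranged from 35173245 to 39642063 per library, so counting error was small for all but genes of low count. Symbols were found in a name table for 60444 IDs, and positions, transcript lengths and GC content for 58368 in GENCODE release 29 on GRCh38, which need not be the release the authors used.

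Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults, libraries scaled by TMM, and genotypes compared by the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg (BH) adjustment over all tested genes and a threshold of 0.05. Fold changes are F133V minus wild-type on the log2 scale, and each SE was taken as the fold change divided by the square root of F. Levels are counts scaled by TMM to a common library size (CPM). The fit leaves 2 residual degrees of freedom and shares the spread across genes; its biological coefficient of variation was 4.64%. The F133V replicates differed from each other by more than sampling noise, with a chi-square over its degrees of freedom of 8.38, as did the wild-type replicates with 1.71, so no library was a copy of another.

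Gene lists, 31 in all, were written before the data were examined: SPOP substrates, CUL3 ligase components, cholesterol and fatty acid synthesis, type I interferon, antigen presentation, NF-kB, mesenchymal, epithelial, luminal, basal and neuroendocrine genes, DNA replication, mitosis, homologous recombination, p53, unfolded protein response, ATF4, NRF2, hypoxia, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, histones, TGF-beta and YAP, extracellular matrix, MAPK, WNT and Hedgehog, hematopoietic, and fibroblast and endothelial markers. A total of 7 genes stand in more than 1 list. Lists with at least 5 tested members, 30 of them, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation 0.01, BH-adjusted over the lists; camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed before the data were examined: SPOP; the 8 largest rises and 8 largest falls among called genes with an ordinary gene symbol, groups that do not overlap and a mean of at least 5 CPM in the higher group; and from each list up to 4 called members of lowest adjusted p if the list passed camera or had 5 or more called members, otherwise up to 2. The rule named 123 genes, of which some are not reported here. Genes outside it are said to have been chosen after their values were seen.

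The GC adjustment was added after the data were seen. Each library's log2 deviation from the gene mean was smoothed on transcript GC content and log2 length (mgcv 1.9.3, basis dimension 8), over genes with a mean log2 CPM above 2, centred on the median and entered as an offset in the same edgeR test; 98.6% of tested genes had a GC value. The coefficient of variation then was 2.46%. In its first form the trend was fitted over all tested genes and centred on the mean. That form was replaced after its result was seen, because its fold changes were off centre for expressed genes, and it is kept as an alternative. An offset on GC content also removes any real difference between genotypes that follows GC content.

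The test was run on simulated counts with 200 of 17539 genes changed. Without a GC trend, edgeR recovered 49 of 50 genes changed 2-fold, 41 of 50 changed 1.5-fold and 28 of 50 changed 1.25-fold, and called 4 of 17339 unchanged genes. With the GC trend of these libraries added, it called 8225 of 17339 unchanged genes, and the adjusted fit called 15 of the 17099 it tested. The added trend was the smooth that the adjustment had itself fitted. Its removal was therefore built in, and the count of 15 does not show how the adjustment performs on the real libraries. That run also used the single spread of the adjusted fit, a coefficient of variation of 2.46%. In a simulation of 30 random lists with 1 list moved, camera called that list and 0 of the 29 others. Genes were drawn independently of each other and without a GC trend, so this run does not test calls for lists of correlated genes.

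Alternatives were other scaling factors, no low-count filter or at least 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, robust empirical Bayes, replicate number as a block, a prior count of 0.5 for the lists, and each library left out in turn. When 1 library is left out its genotype has a single library, which is assumed to vary like the other genotype's. With 2 libraries per genotype, counts of calls under other splits of the samples were not made. Allele-specific counts of SPOP were not analysed here, and neither were mitochondrially encoded genes and the list members TARP and H2AC18.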

Results

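Gene expression was measured by RNA-seq in DU145 cells, an established human prostate cancer cell line, of 2 genotypes: wild-type and cells carrying the F133V form of SPOP. SPOP is the substrate-binding adaptor of a CUL3 ubiquitin ligase, and F133V replaces a phenylalanine of its substrate-binding MATH domain with valine. Each genotype had 2 libraries, replicates 1 and 2. The reads counted in genes numbered 36149516 and 35173245 in the F133V libraries, and 39642063 and 36102260 in the wild-type libraries. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The question was how the SPOP mutation changes gene expression in prostate cancer cells.

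SPOP itself (ENSG00000121067.19, chromosome 17, 49598884 to 49678234 on the minus strand of GRCh38) was measured first. Its level was 1170.3 and 1149.7 CPM, reads scaled to library size, in F133V replicates 1 and 2, and 843 and 905 CPM in wild-type replicates 1 and 2. The means were 1160.0 ± 14.5 CPM in F133V cells and 874 ± 44.2 CPM in wild-type cells (SD, n = 2 each). SPOP rose in F133V cells by a log2 fold change of 0.41 ± 0.055 (SE), which was 0.51 after the GC adjustment (edgeR quasi-likelihood test with Benjamini-Hochberg (BH) adjustment, adjusted p = 2.7e-06 and 1.23e-15). SPOP ranked 77 by count among all genes in both F133V libraries, and 114 and 96 in the wild-type libraries. Gene counts do not separate the mutant from the wild-type transcript, so they do not check which library carries the mutation. SPOP stood high in both genotypes. The labels do not say whether the F133V cells are an edited clone, a pool or an overexpression line. The genotype label of the other cells reads only wild-type, which does not say whether SPOP was added to them. Gene counts do not tell added SPOP from the cells' own, so the rise in SPOP need not be a response to the mutation. An effect of the mutation therefore cannot be told apart from differences in how the cells of each genotype were made.

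F133V cells had more FOS and EGR1 mRNA, 2 immediate-early transcription factors, more mRNA of antigen presentation, inflammatory, epithelial and extracellular matrix genes, and more of nearly every cytosolic ribosomal protein. They had less mRNA of genes for mitosis, homologous recombination, DNA replication and ribosome biogenesis, and less AKR1C1, a ketosteroid reductase. The statements on gene groups rest on counts of members and on camera with a preset correlation. Of all tested genes 54.8% were called before GC adjustment, 49.6% of these as higher. Counts of called members near those shares do not set a list apart. With an estimated correlation 0 of 30 lists passed, the smallest camera BH-adjusted p being 0.293. That correlation is estimated from 2 residual degrees of freedom. These misses therefore cannot tell an absent change from a lack of power, and they do not uphold the calls at the preset correlation. FOS was at 12.8 ± 1.02 CPM in F133V cells and 1.57 ± 0.158 CPM in wild-type cells (SD, n = 2 each), a fold of 8.13, and EGR1 at 151 ± 8.14 CPM in F133V cells and 24.2 ± 4.01 CPM in wild-type cells (SD, n = 2 each), a fold of 6.25. AKR1C1 was at 4.43 ± 0.622 CPM in F133V cells and 21.8 ± 1.88 CPM in wild-type cells (SD, n = 2 each), a fold of 0.204. BRCA2, a homologous recombination protein, was at 13.3 ± 2.28 CPM in F133V cells and 41.9 ± 1.13 CPM in wild-type cells (SD, n = 2 each), a fold of 0.317. GC adjustment moved the log2 fold change of BRCA2 from -1.66 to -0.89.

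Of 17539 genes tested, 9604 differed between the genotypes (edgeR quasi-likelihood test, BH-adjusted p under 0.05), 4763 higher and 4841 lower in F133V cells. Changes of at least 2-fold were seen in 733 of the higher and 492 of the lower genes. The split depended on scaling: with upper-quartile scaling the median log2 fold change of all genes moved from 0.022 to 0.13, and 6462 genes were higher and 3831 lower. Without wild-type replicate 1 or 2, the higher genes numbered 2882 and 2893. The difference between genotypes followed the GC content of each gene's longest transcript. The median log2 difference ran from -0.68 in the lowest of 10 bins of GC content to 0.29 in the highest (Spearman rho 0.73 across 11766 genes, which are not independent replicates). A trend of the same direction separated the F133V replicates from each other (rho 0.77, replicate 2 minus replicate 1), whereas the wild-type replicates gave rho -0.07. A fit adjusted for GC content and transcript length, chosen after the data were seen, called 9057 of 17299 genes, 4963 higher and 4094 lower. As that adjustment was first specified it called 3876 higher and 5448 lower, and it was respecified after this result was seen. In the adjusted fit 3135 genes were higher and 2533 lower as in the fit without it, 3201 calls were lost and 681 turned direction. Genes at least 2-fold changed numbered 539 higher and 117 lower. Values are therefore given from both fits, and those called GC-adjusted are from the second.

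**Figure D1:**
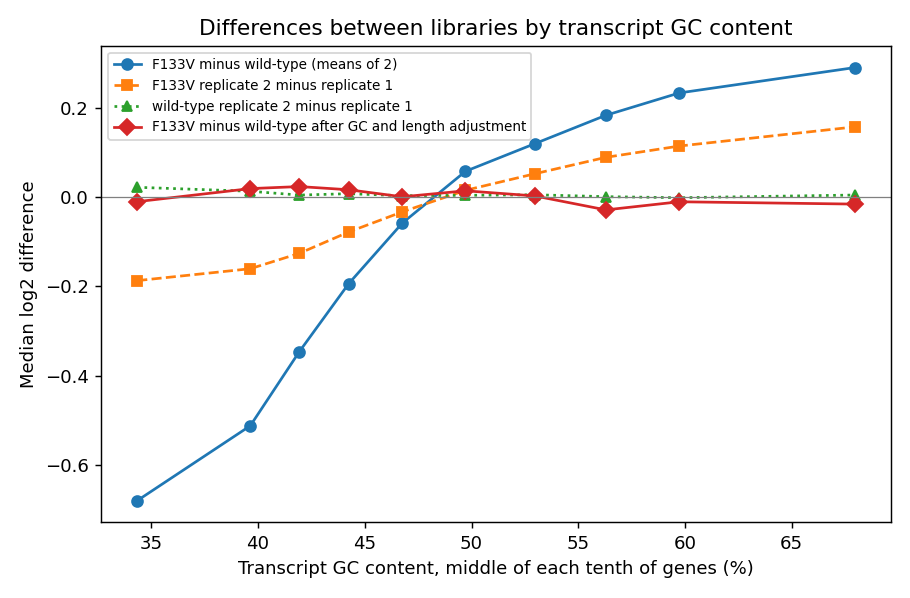
Median log2 difference between libraries (vertical axis) for 10 bins of 11766 genes ordered by transcript GC content in percent (horizontal axis), for F133V against wild-type means, for each pair of replicates, and for the fold change after GC and length adjustment. The genotype difference runs from -0.68 to 0.29, and F133V replicate 2 differs from replicate 1 from -0.19 to 0.16 along the same axis.

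The 8 largest rises and 8 largest falls under the fixed rule are given as log2 fold change ± SE, the first 4 of each with the span of the whole gene in GENCODE release 29 on GRCh38. FOS (ENSG00000170345.10, chromosome 14, 75278774 to 75282230) rose with a log2 fold change of 3.02 ± 0.14 (GC-adjusted 2.87). EGR1 (ENSG00000120738.8, chromosome 5, 138465490 to 138469315) rose with a log2 fold change of 2.64 ± 0.088 (GC-adjusted 2.45). KRT81 (ENSG00000205426.10, chromosome 12, 52285913 to 52291534) rose with a log2 fold change of 2.41 ± 0.092 (GC-adjusted 2.12). CACNA1H (ENSG00000196557.13, chromosome 16, 1153121 to 1221772) rose with a log2 fold change of 2.20 ± 0.14 (GC-adjusted 1.97). CHI3L2 (2.19 ± 0.18, GC-adjusted 2.16), DEPP1 (2.04 ± 0.10, GC-adjusted 1.80), PADI2 (1.93 ± 0.075, GC-adjusted 1.79) and MB (1.88 ± 0.17, GC-adjusted 1.65) followed. The edgeR BH-adjusted p-values of these rises lay between 5.92e-14 and 1.58e-08. KRT81 is a hair keratin, CACNA1H a T-type calcium channel subunit, CHI3L2 a chitinase-like protein, PADI2 a protein-arginine deiminase and MB myoglobin. KRT81 has close paralogs, so its reads are less certainly its own. AKR1C1 (ENSG00000187134.14, chromosome 10, 4963253 to 4983283) fell with a log2 fold change of -2.29 ± 0.11 (GC-adjusted -1.91). BRCA2 (ENSG00000139618.17, chromosome 13, 32315474 to 32400266) fell with a log2 fold change of -1.66 ± 0.094 (GC-adjusted -0.89). CCDC18 (ENSG00000122483.17, chromosome 1, 93179919 to 93278730) fell with a log2 fold change of -1.62 ± 0.11 (GC-adjusted -1.04). PPP4R4 (ENSG00000119698.12, chromosome 14, 94146128 to 94279735) fell with a log2 fold change of -1.54 ± 0.10 (GC-adjusted -1.0). DLEU2 (-1.52 ± 0.17, GC-adjusted -1.48), ASPM (-1.51 ± 0.082, GC-adjusted -0.78), CENPE (-1.50 ± 0.092, GC-adjusted -0.72) and FAM111B (-1.49 ± 0.087, GC-adjusted -0.87) followed. For the falls, the edgeR BH-adjusted p-values lay between 1.03e-11 and 2.37e-07. ASPM is a spindle pole protein, CENPE a kinetochore motor and DLEU2 a long noncoding RNA gene. AKR1C1 is nearly identical in sequence to AKR1C2, so reads could be split between them.

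**Figure D2:**
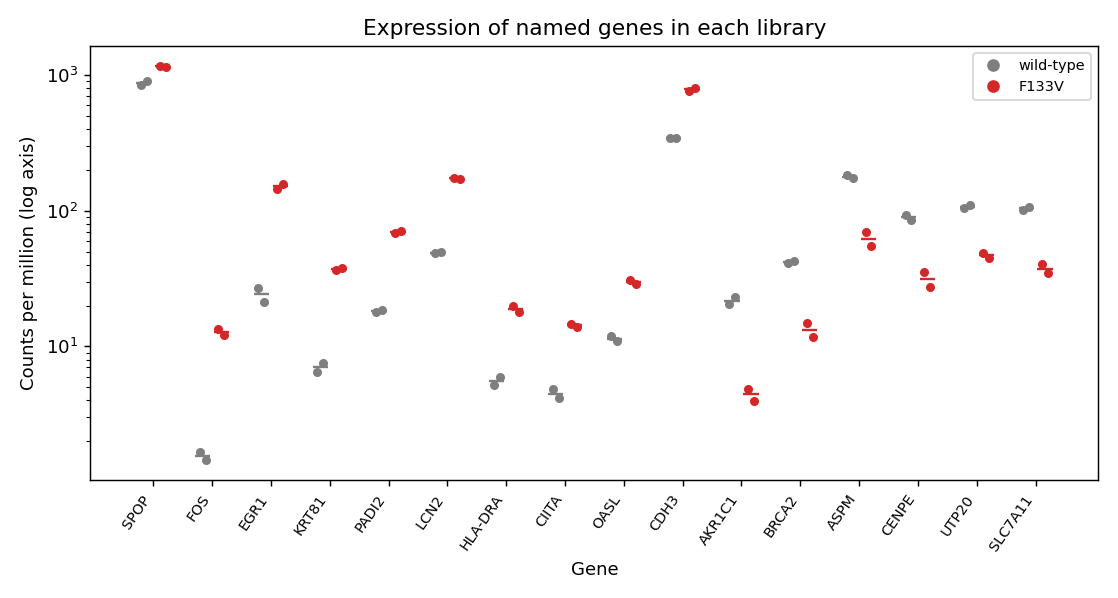
CPM on a log axis (vertical) for SPOP and 15 other named genes (horizontal), with 1 point per library, grey for wild-type and red for F133V, and a line at each mean of 2. The points of the genotypes do not overlap for these genes, which was a condition of choice for the largest rises and falls. Of all tested genes, 78.0% had groups that do not overlap.

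Cell division genes were lower in F133V cells. In the mitosis list, 1 of 39 measured members rose, 28 fell and 10 did not pass; adjusted over the list alone, 1 was higher and 28 lower. The mitosis median was -0.52 (camera BH-adjusted p = 2.53e-09, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the mitosis median was -0.25, with 0 members higher and 31 lower (camera BH-adjusted p = 3.61e-14, and adjusted p = 0.202 with an estimated correlation). ASPM and CENPE, above, had the lowest p-values. ANLN (-1.07 ± 0.068, GC-adjusted -0.57), a cytokinesis scaffold, and ECT2 (-1.07 ± 0.069, GC-adjusted -0.47), a RhoA exchange factor of cytokinesis, also fell. In the homologous recombination and DNA damage checkpoint list, 0 of 36 measured members rose, 26 fell and 10 did not pass; adjusted over the list alone, 0 were higher and 26 lower. The homologous recombination and DNA damage checkpoint median was -0.67 (camera BH-adjusted p = 3.44e-09, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the homologous recombination and DNA damage checkpoint median was -0.27, with 0 members higher and 27 lower (camera BH-adjusted p = 2.15e-09, and adjusted p = 0.202 with an estimated correlation). BRCA2, above, and BRCA1 (-1.08 ± 0.076, GC-adjusted -0.66) fell. So did the checkpoint kinase ATR (-1.29 ± 0.08, GC-adjusted -0.72) and its activator TOPBP1 (-0.97 ± 0.072, GC-adjusted -0.64). In the DNA replication list, 4 of 37 measured members rose, 21 fell and 12 did not pass; adjusted over the list alone, 4 were higher and 22 lower. The DNA replication median was -0.23 (camera BH-adjusted p = 0.00156, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the DNA replication median was -0.19, with 0 members higher and 27 lower (camera BH-adjusted p = 2.02e-08, and adjusted p = 0.202 with an estimated correlation). RFC3 (-0.93 ± 0.073, GC-adjusted -0.41) of the clamp loader and the cyclin CCNE2 (-1.11 ± 0.092, GC-adjusted -0.47) fell. The polymerase subunit POLA1 (-0.89 ± 0.084, GC-adjusted -0.57) and MCM10 (-0.74 ± 0.073, GC-adjusted -0.47) fell as well. The median GC content was 43.2% in the mitosis list and 42.3% in the recombination list, in the range where F133V values lay lower along the GC trend.

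Ribosome biogenesis factors were lower and ribosomal proteins higher. In the MYC target and ribosome biogenesis list, 1 of 38 measured members rose, 29 fell and 8 did not pass; adjusted over the list alone, 1 was higher and 29 lower. The MYC target and ribosome biogenesis median was -0.32 (camera BH-adjusted p = 5.56e-07, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the MYC target and ribosome biogenesis median was -0.41, with 1 member higher and 33 lower (camera BH-adjusted p = 7.54e-17, and adjusted p = 0.202 with an estimated correlation). The small-subunit processome proteins UTP20 (-1.19 ± 0.069, GC-adjusted -0.77) and WDR43 (-0.95 ± 0.069, GC-adjusted -0.49) fell. The nucleolar helicase DDX21 (-0.90 ± 0.065, GC-adjusted -0.47) and the box C/D snoRNP protein NOP58 (-1.01 ± 0.077, GC-adjusted -0.65) fell too. In the cytosolic ribosomal protein list, 63 of 66 measured members rose, 0 fell and 3 did not pass; adjusted over the list alone, 63 were higher and 0 lower. The cytosolic ribosomal protein median was 0.37 (camera BH-adjusted p = 3.66e-18, and adjusted p = 0.306 with an estimated correlation). GC-adjusted, the cytosolic ribosomal protein median was 0.34, with 57 members higher and 0 lower (camera BH-adjusted p = 3.77e-24, and adjusted p = 0.278 with an estimated correlation). RPL13A (0.58 ± 0.053, GC-adjusted 0.36) and RPL9 (0.52 ± 0.053, GC-adjusted 0.94) rose, as did RPL4 (0.46 ± 0.051, GC-adjusted 0.56). Ribosomal protein genes have many processed pseudogenes, and reads with several alignments stood in a tally outside the gene counts. Those reads made up 15.1% and 16.6% in F133V replicates 1 and 2, and 14.6% and 13.6% in wild-type replicates 1 and 2. Whether this difference bears on the ribosomal protein counts was not tested.

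The list of nuclear-encoded oxidative phosphorylation subunits was called higher by camera, at a smaller median than the ribosomal proteins. In the oxidative phosphorylation list, 27 of 58 measured members rose, 3 fell and 28 did not pass; adjusted over the list alone, 26 were higher and 3 lower. The oxidative phosphorylation median was 0.14 (camera BH-adjusted p = 0.00859, and adjusted p = 0.441 with an estimated correlation). GC-adjusted, the oxidative phosphorylation median was 0.10, with 28 members higher and 7 lower (camera BH-adjusted p = 0.00132, and adjusted p = 0.434 with an estimated correlation). The unadjusted call was lost without wild-type replicate 2 (camera BH-adjusted p = 0.10). NDUFA2 (0.34 ± 0.07, GC-adjusted 0.15) and NDUFS7 (0.37 ± 0.075, GC-adjusted 0.12) rose. NDUFS7 missed under the GC correction as first specified (edgeR BH-adjusted p = 0.676) and with GC and length without F133V replicate 2 (0.171). NDUFV1 (0.30 ± 0.063, GC-adjusted 0.04) and ATP5F1D (0.35 ± 0.074, GC-adjusted 0.026) passed before GC adjustment (edgeR BH-adjusted p = 3.67e-04 and 4.72e-04) and not after it (0.349 and 0.607). NDUFV1 also missed without wild-type replicate 2 (edgeR BH-adjusted p = 0.0650). In the replication-dependent histone list, 6 of 18 measured members rose, 2 fell and 10 did not pass; adjusted over the list alone, 6 were higher and 2 lower. The replication-dependent histone median was 0.22 (camera BH-adjusted p = 0.175, and adjusted p = 0.441 with an estimated correlation). GC-adjusted, the replication-dependent histone median was 0.15, with 5 members higher and 4 lower (camera BH-adjusted p = 0.759, and adjusted p = 0.885 with an estimated correlation). H2BC5 (0.60 ± 0.09, GC-adjusted 0.54) and H2AC8 (0.99 ± 0.17, GC-adjusted 0.66) rose. H4C8 (-0.49 ± 0.11, GC-adjusted -0.30) fell. With GC and length adjusted and F133V replicate 2 left out, H4C8 gave -0.20 and missed (edgeR BH-adjusted p = 0.0960). Histone genes share near-identical sequences. Mitochondrially encoded genes, a list of 15, were not analysed here.

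Immune-related genes were higher in F133V cells. In the antigen presentation list, 17 of 24 measured members rose, 2 fell and 5 did not pass; adjusted over the list alone, 17 were higher and 2 lower. The antigen presentation median was 0.39 (camera BH-adjusted p = 2.29e-06, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the antigen presentation median was 0.30, with 17 members higher and 1 lower (camera BH-adjusted p = 3.71e-07, and adjusted p = 0.235 with an estimated correlation). The MHC class II transactivator CIITA (1.67 ± 0.11, GC-adjusted 1.66) and the class II genes HLA-DRA (1.76 ± 0.10, GC-adjusted 1.75) and HLA-DRB1 (1.05 ± 0.091, GC-adjusted 0.83) rose. The invariant chain CD74 (1.31 ± 0.071, GC-adjusted 1.03) rose, at 95.2 ± 0.116 CPM in F133V cells and 38.4 ± 2.86 CPM in wild-type cells (SD, n = 2 each). Hematopoietic markers, 5 of them tested, had a median of 0.58 in the same direction. Class II genes are near-identical to each other in parts, so single-gene counts are uncertain. In the type I interferon list, 23 of 39 measured members rose, 8 fell and 8 did not pass; adjusted over the list alone, 24 were higher and 9 lower. The type I interferon median was 0.37 (camera BH-adjusted p = 0.00486, and adjusted p = 0.430 with an estimated correlation). GC-adjusted, the type I interferon median was 0.39, with 26 members higher and 2 lower (camera BH-adjusted p = 6.33e-06, and adjusted p = 0.382 with an estimated correlation). The unadjusted call was lost without F133V replicate 1 (camera BH-adjusted p = 0.0588). OASL (1.39 ± 0.086, GC-adjusted 1.29) and IFI6 (1.17 ± 0.10, GC-adjusted 0.90) rose. The close paralogs IFITM2 (0.91 ± 0.073, GC-adjusted 0.66) and IFITM3 (0.93 ± 0.071, GC-adjusted 0.65) rose as well. In the NF-kB and inflammatory list, 20 of 32 measured members rose, 4 fell and 8 did not pass; adjusted over the list alone, 20 were higher and 4 lower. The NF-kB and inflammatory median was 0.35 (camera BH-adjusted p = 0.00108, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the NF-kB and inflammatory median was 0.27, with 20 members higher and 5 lower (camera BH-adjusted p = 6.29e-05, and adjusted p = 0.202 with an estimated correlation). Lipocalin LCN2 (1.82 ± 0.064, GC-adjusted 1.54) and complement C3 (0.85 ± 0.061, GC-adjusted 0.67) rose. The cytokines CSF2 (1.01 ± 0.10, GC-adjusted 0.87) and CCL5 (1.39 ± 0.18, GC-adjusted 1.21) also rose. LCN2 was at 173 ± 0.922 CPM in F133V cells and 49.1 ± 0.293 CPM in wild-type cells (SD, n = 2 each).

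Epithelial and matrix genes were also higher. In the epithelial list, 20 of 30 measured members rose, 6 fell and 4 did not pass; adjusted over the list alone, 21 were higher and 6 lower. The epithelial median was 0.48 (camera BH-adjusted p = 2.27e-05, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the epithelial median was 0.31, with 22 members higher and 4 lower (camera BH-adjusted p = 3.15e-06, and adjusted p = 0.202 with an estimated correlation). P-cadherin CDH3 (1.19 ± 0.055, GC-adjusted 1.05) and the mucin MUC1 (1.29 ± 0.06, GC-adjusted 0.83) rose. The tight junction protein TJP3 (1.49 ± 0.10, GC-adjusted 1.22) and the protease matriptase ST14 (1.01 ± 0.078, GC-adjusted 0.75) rose too. CDH3 was at 785 ± 25.9 CPM in F133V cells and 345 ± 1.11 CPM in wild-type cells (SD, n = 2 each). In the extracellular matrix and integrin list, 23 of 34 measured members rose, 6 fell and 5 did not pass; adjusted over the list alone, 23 were higher and 6 lower. The extracellular matrix and integrin median was 0.36 (camera BH-adjusted p = 7.61e-05, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the extracellular matrix and integrin median was 0.28, with 24 members higher and 3 lower (camera BH-adjusted p = 3.13e-06, and adjusted p = 0.238 with an estimated correlation). The collagens COL6A2 (0.59 ± 0.058, GC-adjusted 0.28) and COL5A1 (1.45 ± 0.15, GC-adjusted 1.3) rose, as did fibulin FBLN1 (0.78 ± 0.077, GC-adjusted 0.55) and the integrin ITGB3 (0.72 ± 0.078, GC-adjusted 0.62). Fibroblast and endothelial markers, 5 of them tested, had a median of 1.28 in the same direction. In the mesenchymal list, 14 of 22 measured members rose, 5 fell and 3 did not pass; adjusted over the list alone, 15 were higher and 5 lower. The mesenchymal median was 0.25 (camera BH-adjusted p = 0.0774, and adjusted p = 0.315 with an estimated correlation). GC-adjusted, the mesenchymal median was 0.21, with 12 members higher and 5 lower (camera BH-adjusted p = 0.0613, and adjusted p = 0.434 with an estimated correlation). As counted, the mesenchymal list passed as higher with no low-count filter (camera BH-adjusted p = 0.0263) and without F133V replicate 2 (0.0405). It also passed under the GC correction as first specified (camera BH-adjusted p = 0.0419), and not with GC alone (0.0672). TAGLN (1.21 ± 0.074, GC-adjusted 1.0) and the protease MMP14 (0.94 ± 0.06, GC-adjusted 0.71) rose. The transcription factors ZEB1 (-1.10 ± 0.095, GC-adjusted -0.49) and SNAI2 (-0.98 ± 0.14, GC-adjusted -0.60) fell.

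The lists of luminal, basal and neuroendocrine identity did not pass. In the luminal and androgen response list, 8 of 17 measured members rose, 6 fell and 3 did not pass; adjusted over the list alone, 8 were higher and 6 lower. The luminal and androgen response median was 0.12 (camera BH-adjusted p = 0.570, and adjusted p = 0.684 with an estimated correlation). GC-adjusted, the luminal and androgen response median was 0.12, with 9 members higher and 1 lower (camera BH-adjusted p = 0.116, and adjusted p = 0.380 with an estimated correlation). ALDH1A3 (0.73 ± 0.063, GC-adjusted 0.65) and NDRG1 (0.67 ± 0.058, GC-adjusted 0.57) rose. ZBTB10 (-0.67 ± 0.075, GC-adjusted -0.07) and FKBP5 (-0.53 ± 0.062, GC-adjusted -0.08) fell before GC adjustment and missed after it (edgeR BH-adjusted p = 0.223 and 0.0670). Both passed as lower under the GC correction as first specified (edgeR BH-adjusted p = 0.00452 and 3.53e-04) and with GC alone (0.00763 and 0.00295), and FKBP5 also with GC and length without F133V replicate 2 (0.00404). In the basal prostate list, 7 of 16 measured members rose, 6 fell and 3 did not pass; adjusted over the list alone, 7 were higher and 6 lower. The basal prostate median was 0.16 (camera BH-adjusted p = 0.820, and adjusted p = 0.863 with an estimated correlation). GC-adjusted, the basal prostate median was 0.0084, with 6 members higher and 6 lower (camera BH-adjusted p = 0.544, and adjusted p = 0.745 with an estimated correlation). The GC-adjusted basal test pointed down against that small positive median. DST (-1.07 ± 0.075, GC-adjusted -0.58) and ITGA6 (-0.60 ± 0.059, GC-adjusted -0.28) fell. ITGB4 (0.40 ± 0.072, GC-adjusted 0.17) and NGFR (1.22 ± 0.23, GC-adjusted 0.96) rose. ITGB4 missed under the correction as first specified (log2 fold change 0.058, edgeR BH-adjusted p = 0.214). In the neuroendocrine list, 1 of 9 measured members rose, 2 fell and 6 did not pass; adjusted over the list alone, 1 was higher and 1 lower. The neuroendocrine median was 0.10 (camera BH-adjusted p = 0.658, and adjusted p = 0.738 with an estimated correlation). GC-adjusted, the neuroendocrine median was 0.091, with 3 members higher and 4 lower (camera BH-adjusted p = 0.759, and adjusted p = 0.822 with an estimated correlation). The GC-adjusted neuroendocrine test likewise pointed down. ENO2 (0.49 ± 0.061, GC-adjusted 0.30) rose and EZH2 (-0.48 ± 0.069, GC-adjusted -0.17) fell.

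**Figure D3:**
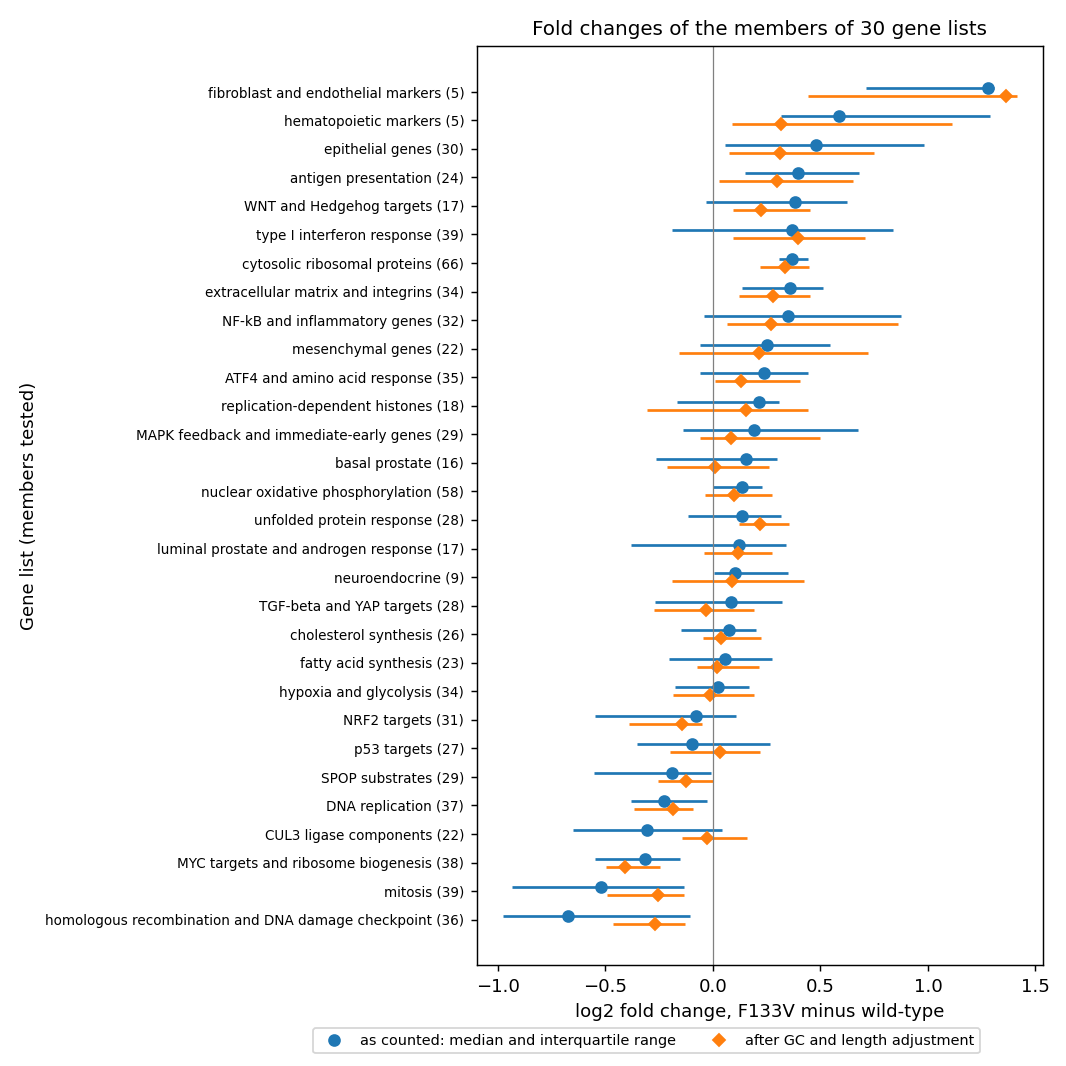
Median (points) and interquartile range (lines) of the log2 fold change, F133V minus wild-type (horizontal axis), over the tested members of 30 gene lists (vertical axis, member number in brackets), as counted in blue and after GC and length adjustment in orange. The recombination and mitosis medians lie at -0.67 and -0.52 as counted and at -0.27 and -0.25 after adjustment, and ribosomal proteins at 0.37 and 0.34.

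Among stress lists, camera called the ATF4 list higher and the NRF2 list lower. In the ATF4 and amino acid response list, 20 of 35 measured members rose, 7 fell and 8 did not pass; adjusted over the list alone, 22 were higher and 7 lower. The ATF4 and amino acid response median was 0.24 (camera BH-adjusted p = 0.00595, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the ATF4 and amino acid response median was 0.13, with 20 members higher and 6 lower (camera BH-adjusted p = 0.00442, and adjusted p = 0.235 with an estimated correlation). DDIT4 (0.93 ± 0.06, GC-adjusted 0.66), CEBPB (0.80 ± 0.062, GC-adjusted 0.45) and the serine synthesis enzyme PHGDH (0.56 ± 0.058, GC-adjusted 0.44) rose. The cystine transporter SLC7A11 (-1.47 ± 0.075, GC-adjusted -0.68), which is also on the NRF2 list, fell. In the NRF2 target list, 5 of 31 measured members rose, 15 fell and 11 did not pass; adjusted over the list alone, 5 were higher and 15 lower. The NRF2 target median was -0.078 (camera BH-adjusted p = 0.0465, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the NRF2 target median was -0.14, with 4 members higher and 22 lower (camera BH-adjusted p = 2.64e-05, and adjusted p = 0.202 with an estimated correlation). The unadjusted NRF2 call was lost with upper-quartile scaling (camera BH-adjusted p = 0.104), DESeq2's scaling factors (0.0531) and library size alone (0.0752). It was also lost with the stricter low-count filter (camera BH-adjusted p = 0.0806) and without F133V replicate 1 (0.0599). AKR1C1, AKR1C2 (-1.47 ± 0.13, GC-adjusted -1.0) and GCLM (-0.79 ± 0.073, GC-adjusted -0.15) of glutathione synthesis fell. In the unfolded protein response list, 13 of 28 measured members rose, 6 fell and 9 did not pass; adjusted over the list alone, 15 were higher and 6 lower. The unfolded protein response median was 0.14 (camera BH-adjusted p = 0.114, and adjusted p = 0.621 with an estimated correlation). GC-adjusted, the unfolded protein response median was 0.22, with 21 members higher and 0 lower (camera BH-adjusted p = 6.33e-06, and adjusted p = 0.326 with an estimated correlation). As counted, this list passed as higher with upper-quartile scaling (camera BH-adjusted p = 0.0427) and without F133V replicate 2 (0.0300). EDEM2 (0.50 ± 0.067, GC-adjusted 0.30), CALR (0.35 ± 0.053, GC-adjusted 0.16) and PDIA6 (0.33 ± 0.053, GC-adjusted 0.41) rose. DNAJC3 (-0.62 ± 0.083, GC-adjusted -0.10) fell before GC adjustment and missed after it (edgeR BH-adjusted p = 0.0977). It passed as lower under the correction as first specified (edgeR BH-adjusted p = 0.00452). In the p53 target list, 8 of 27 measured members rose, 10 fell and 9 did not pass; adjusted over the list alone, 8 were higher and 10 lower. The p53 target median was -0.10 (camera BH-adjusted p = 0.820, and adjusted p = 0.854 with an estimated correlation). GC-adjusted, the p53 target median was 0.034, with 10 members higher and 8 lower (camera BH-adjusted p = 0.957, and adjusted p = 0.957 with an estimated correlation). The unadjusted p53 mean was 0.015, of the other sign than the median. BBC3 (1.20 ± 0.12, GC-adjusted 0.74) rose. RRM2B (-0.92 ± 0.08, GC-adjusted -0.24), AEN (-0.90 ± 0.084, GC-adjusted -0.95) and FAS (-0.82 ± 0.094, GC-adjusted -0.31) fell.

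The hypoxia, cholesterol and fatty acid lists did not pass. In the hypoxia and glycolysis list, 9 of 34 measured members rose, 9 fell and 16 did not pass; adjusted over the list alone, 9 were higher and 9 lower. The hypoxia and glycolysis median was 0.026 (camera BH-adjusted p = 0.664, and adjusted p = 0.863 with an estimated correlation). GC-adjusted, the hypoxia and glycolysis median was -0.014, with 11 members higher and 11 lower (camera BH-adjusted p = 0.849, and adjusted p = 0.956 with an estimated correlation). The glucose transporter SLC2A3 (1.53 ± 0.12, GC-adjusted 1.64) rose, as did NDRG1, which is on this list too. BNIP3L (-0.48 ± 0.061, GC-adjusted 0.074) and PDK1 (-0.52 ± 0.071, GC-adjusted 0.086) fell before GC adjustment and missed after it (edgeR BH-adjusted p = 0.0652 and 0.124). With GC alone BNIP3L passed as higher (edgeR BH-adjusted p = 0.0202). In the cholesterol synthesis list, 8 of 26 measured members rose, 5 fell and 13 did not pass; adjusted over the list alone, 8 were higher and 5 lower. The cholesterol synthesis median was 0.074 (camera BH-adjusted p = 0.604, and adjusted p = 0.672 with an estimated correlation). GC-adjusted, the cholesterol synthesis median was 0.037, with 9 members higher and 3 lower (camera BH-adjusted p = 0.374, and adjusted p = 0.505 with an estimated correlation). TM7SF2 (0.80 ± 0.077, GC-adjusted 0.48) and the regulator SREBF2 (0.41 ± 0.059, GC-adjusted 0.23) rose. HMGCS1 (-0.51 ± 0.067, GC-adjusted -0.036) and SC5D (-0.53 ± 0.083, GC-adjusted 0.0039) fell before GC adjustment and missed after it (edgeR BH-adjusted p = 0.442 and 0.956). HMGCS1 passed as lower under the correction as first specified (edgeR BH-adjusted p = 0.00980). In the fatty acid synthesis list, 9 of 23 measured members rose, 6 fell and 8 did not pass; adjusted over the list alone, 9 were higher and 6 lower. The fatty acid synthesis median was 0.057 (camera BH-adjusted p = 0.664, and adjusted p = 0.744 with an estimated correlation). GC-adjusted, the fatty acid synthesis median was 0.02, with 10 members higher and 5 lower (camera BH-adjusted p = 0.543, and adjusted p = 0.621 with an estimated correlation). The unadjusted fatty acid mean was -0.0049, below 0. DGAT2 (0.75 ± 0.075, GC-adjusted 0.68) rose. GPAM (-0.89 ± 0.082, GC-adjusted -0.42) and ACSL4 (-0.78 ± 0.077, GC-adjusted -0.14) fell. ME1 (-0.57 ± 0.069, GC-adjusted -0.06) fell before GC adjustment and missed after it (edgeR BH-adjusted p = 0.220). ME1 too passed as lower under the first form (edgeR BH-adjusted p = 0.00429).

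The mRNAs of the list written as SPOP substrates, proteins reported to interact with the ligase, were called lower as a list by camera. Whether each member, G3BP1 among them, is regulated by the ligase at the protein level was not examined here. In the SPOP substrate list, 2 of 29 measured members rose, 14 fell and 13 did not pass; adjusted over the list alone, 2 were higher and 14 lower. The SPOP substrate median was -0.19 (camera BH-adjusted p = 0.0120, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the SPOP substrate median was -0.13, with 5 members higher and 13 lower (camera BH-adjusted p = 0.0104, and adjusted p = 0.238 with an estimated correlation). DEK (-0.98 ± 0.074, GC-adjusted -0.52) fell in both fits. G3BP1 (-0.70 ± 0.06, GC-adjusted -0.022), ATF2 (-0.72 ± 0.078, GC-adjusted -0.068) and SENP7 (-0.87 ± 0.10, GC-adjusted -0.16) fell before GC adjustment and missed after it (edgeR BH-adjusted p = 0.608, 0.247 and 0.0801). All 3 passed as lower under the GC correction as first specified (edgeR BH-adjusted p = 0.00821, 0.0230 and 0.0202), and G3BP1 also with GC alone (0.0118). In the CUL3 ligase component list, 3 of 22 measured members rose, 12 fell and 7 did not pass; adjusted over the list alone, 3 were higher and 12 lower. The CUL3 ligase component median was -0.30 (camera BH-adjusted p = 0.0106, and adjusted p = 0.344 with an estimated correlation). GC-adjusted, the CUL3 ligase component median was -0.029, with 7 members higher and 6 lower (camera BH-adjusted p = 0.849, and adjusted p = 0.885 with an estimated correlation). NAE1 (-0.79 ± 0.069, GC-adjusted -0.38) of the NEDD8-activating enzyme fell in both fits. DCUN1D1 (-0.86 ± 0.083, GC-adjusted -0.056), CAND1 (-0.69 ± 0.067, GC-adjusted -0.071) and the SPOP paralog SPOPL (-0.84 ± 0.083, GC-adjusted -0.13) fell before GC adjustment and missed after it (edgeR BH-adjusted p = 0.345, 0.0820 and 0.118). These 3 also passed as lower under the correction as first specified (edgeR BH-adjusted p = 0.0473, 1.84e-04 and 0.0249). CAND1 passed with GC alone (edgeR BH-adjusted p = 2.58e-04), and SPOPL with GC and length without F133V replicate 2 (0.0277).

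Among signalling lists, the MAPK and WNT lists were called higher by camera as counted, and the WNT list did not pass after GC adjustment. In the MAPK feedback and immediate-early list, 13 of 29 measured members rose, 5 fell and 11 did not pass; adjusted over the list alone, 13 were higher and 7 lower. The MAPK feedback and immediate-early median was 0.19 (camera BH-adjusted p = 0.0367, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the MAPK feedback and immediate-early median was 0.085, with 12 members higher and 6 lower (camera BH-adjusted p = 0.0407, and adjusted p = 0.336 with an estimated correlation). The unadjusted MAPK call was lost with DESeq2's scaling factors (camera BH-adjusted p = 0.0534). FOS and EGR1, above, rose with IER2 (0.90 ± 0.077, GC-adjusted 0.63) and JUNB (0.83 ± 0.073, GC-adjusted 0.50), all immediate-early genes. In a split of the list made after the data were seen, the 13 ERK feedback genes had a GC-adjusted median of -0.053, with 3 higher and 5 lower. The 9 other immediate-early genes tested had 0.31, with 5 higher and 0 lower. They include IER2 and JUNB. FOS, EGR1, EREG, AREG, HBEGF, TGFA and CCND1 were in neither set. In the WNT and Hedgehog list, 9 of 17 measured members rose, 1 fell and 7 did not pass; adjusted over the list alone, 9 were higher and 1 lower. The WNT and Hedgehog median was 0.38 (camera BH-adjusted p = 0.0186, and adjusted p = 0.293 with an estimated correlation). GC-adjusted, the WNT and Hedgehog median was 0.23, with 8 members higher and 1 lower (camera BH-adjusted p = 0.239, and adjusted p = 0.519 with an estimated correlation). The unadjusted WNT call was also lost without F133V replicate 1 (camera BH-adjusted p = 0.0529). The WNT feedback inhibitors NOTUM (1.08 ± 0.11, GC-adjusted 0.73), NKD1 (0.95 ± 0.11, GC-adjusted 0.96) and NKD2 (0.61 ± 0.083, GC-adjusted 0.23) rose. The WNT antagonist DKK1 (-0.71 ± 0.068, GC-adjusted -0.51) fell. In the TGF-beta and YAP list, 11 of 28 measured members rose, 8 fell and 9 did not pass; adjusted over the list alone, 11 were higher and 8 lower. The TGF-beta and YAP median was 0.084 (camera BH-adjusted p = 0.653, and adjusted p = 0.743 with an estimated correlation). GC-adjusted, the TGF-beta and YAP median was -0.033, with 10 members higher and 9 lower (camera BH-adjusted p = 0.759, and adjusted p = 0.822 with an estimated correlation). The unadjusted TGF-beta mean was -0.0012, below 0. ANKRD1 (0.87 ± 0.082, GC-adjusted 1.09) and LTBP2 (0.62 ± 0.063, GC-adjusted 0.49) rose. Tissue factor F3 (-1.02 ± 0.065, GC-adjusted -0.82) and thrombospondin THBS1 (-0.71 ± 0.065, GC-adjusted -0.52) fell.

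Markers of other cell types were few and low, with 5 of 21 hematopoietic and 5 of 15 fibroblast and endothelial markers tested. In the hematopoietic marker list, 3 of 5 measured members rose, 0 fell and 2 did not pass; adjusted over the list alone, 4 were higher and 0 lower. The hematopoietic marker median was 0.58 (camera BH-adjusted p = 0.123, and adjusted p = 0.370 with an estimated correlation). GC-adjusted, the hematopoietic marker median was 0.32, with 2 members higher and 0 lower (camera BH-adjusted p = 0.508, and adjusted p = 0.621 with an estimated correlation). ITGAX (1.29 ± 0.32, GC-adjusted 1.11) was at 1.17 ± 0.419 CPM in F133V cells and 0.488 ± 0.221 CPM in wild-type cells (SD, n = 2 each). It missed the test without F133V replicate 1 (edgeR BH-adjusted p = 0.0501). ITGAM (1.3 ± 0.35, GC-adjusted 1.16) missed with DESeq2 (BH-adjusted p = 0.0799) and, GC-adjusted, without F133V replicate 2 (edgeR BH-adjusted p = 0.0565). In the fibroblast and endothelial marker list, 4 of 5 measured members rose, 0 fell and 1 did not pass; adjusted over the list alone, 4 were higher and 0 lower. The fibroblast and endothelial marker median was 1.28 (camera BH-adjusted p = 0.0625, and adjusted p = 0.315 with an estimated correlation). GC-adjusted, the fibroblast and endothelial marker median was 1.36, with 3 members higher and 0 lower (camera BH-adjusted p = 0.155, and adjusted p = 0.413 with an estimated correlation). The fibroblast and endothelial list passed as higher with no low-count filter (camera BH-adjusted p = 0.0326) and without wild-type replicate 1 (0.0270) or 2 (0.0446), and camera's adjusted p lay between 0.0270 and 0.315 over the alternatives. COL14A1 (1.31 ± 0.16, GC-adjusted 1.41) was at 5.11 ± 1.06 CPM in F133V cells and 2.07 ± 0.0303 CPM in wild-type cells (SD, n = 2 each). VWF (2.07 ± 0.54, GC-adjusted 1.94) was at 0.348 ± 0.0686 CPM in F133V cells and 0.0789 ± 0.0324 CPM in wild-type cells (SD, n = 2 each). Over all lists, camera called 10 higher and 7 lower of 30 with its preset correlation. With an estimated correlation it called 0 after BH adjustment and 1 at an unadjusted p under 0.05. In the GC-adjusted fit camera called 10 higher and 6 lower, and with an estimated correlation 0 after BH adjustment and 7 at an unadjusted p under 0.05. The test fry, which asks of each list alone whether its genes move one way, called 24.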

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

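Some shares of reads outside the gene counts were higher in both F133V libraries than in both wild-type libraries, a difference that was not tested, and the explanations of the patterns in this part were tested only after the results were seen, except the tests of transcript length within 10 bins of GC content. Reads aligned at more than 1 place made up 15.1% and 16.6% of all reads in F133V replicates 1 and 2, above the 14.6% and 13.6% of the wild-type libraries, with replicate 1 of the genotypes closer together than the replicates within each genotype. Reads over more than 1 gene made up 3.73% and 3.69% in the F133V replicates, above the 3.50% and 3.52% of the wild-type libraries.

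The first pattern is that fold changes followed transcript GC content. A GC bias that differs between libraries may account for much of it, since the F133V replicates, which share a genotype, differed from each other along the same trend with a Spearman rho of 0.773. An effect of the genotype on AT-rich transcripts cannot be told apart from a bias of both F133V libraries, because the rho was at least 0.653 in all 4 pairs of libraries of different genotype and both F133V libraries stand on the same side. Transcript length as the whole driver is argued against. The genotype difference followed GC content with a rho of at least 0.499 within each of 10 bins of length. Within 10 bins of GC content a median rho of -0.110 with length was left, between the bounds set for that test. The rho with length was -0.367 in the bin of lowest GC content and -0.0176 in the highest. A part played by length among AT-rich transcripts therefore stays open. The GC trend as the whole cause of the lower cell division genes is argued against by medians after adjustment of -0.254 for mitosis, -0.268 for homologous recombination and -0.186 for DNA replication, each with its upper quartile below 0 and its camera call kept at the preset correlation, though not with an estimated one (adjusted p = 0.202 for each).

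The second pattern is that FOS and EGR1 rose. The GC trend as the whole cause is argued against, as both passed the adjusted test and kept at least 92.8% of their log2 fold change. A transient stimulus at harvest may account for the rise, but the test made here cannot single it out. The other immediate-early genes had a median adjusted log2 fold change of 0.307, with 5 higher and 0 lower of 9. That set was drawn after the data were seen and includes IER2 and JUNB, already named for their rise. A rise of such genes does not tell a stimulus at harvest from sustained signalling or from genotype. The 13 ERK feedback genes had a median of -0.0525, with 3 higher and 5 lower. That median met the bound set against sustained ERK signalling, which was 0 or below. Its quartiles of -0.185 and 0.157 lay on both sides of 0, so sustained ERK signalling was not called excluded and stays open. Genotype and any difference in handling or cell density between the cultures were not tested apart.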

How the results depend on the processing

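The corrections for GC content were chosen after the data were seen; all other alternatives were fixed before. SPOP was higher in F133V cells under every alternative run, with a log2 fold change of 0.36 to 0.53. Of 2408 values of 142 named genes other than SPOP over 17 alternatives, 2352 kept their direction and side of the threshold, 44 lost the call and 12 turned direction. Of 478 values of 30 lists over 16 alternatives, 409 were kept, 32 lost the call, 18 gained it and 19 turned direction. The 9604 genes called became 7256 with DESeq2. Genes at least 2-fold changed, 1225 in all, numbered 714 with the stricter low-count filter, which tests fewer genes, and 656 with GC and length correction, 680 with GC correction alone, 615 with the correction as first specified and 681 with GC and length correction and F133V replicate 2 left out. The correction as first specified gave 41.6% of its 9324 calls as higher, against 54.8% as respecified and 49.6% without correction; upper-quartile scaling gave 62.8%. Genes higher in F133V cells numbered 2882 to 5189 when each library was left out, 2882 without wild-type replicate 1 and 2893 without wild-type replicate 2. Gene lists called fell from 17 to 0 with an estimated correlation (0 higher and 0 lower), and fry gave 17 higher lists against 10; fry asks a different question of each list.

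The named genes that turned direction did so under the GC corrections, which remove the trend. SC5D gave 0.0039 with GC and length, 0.054 with GC alone and 0.057 without F133V replicate 2. BNIP3L gave 0.074, 0.095 and 0.056 in that order, and with GC alone it passed as higher (edgeR BH-adjusted p = 0.0202). PDK1 gave 0.086 with GC and length, 0.0060 as first specified and 0.039 without F133V replicate 2. NDUFV1 gave -0.043 as first specified, and ATP5F1D -0.067 as first specified and -0.020 without F133V replicate 2. The lists that turned direction passed under no setting in which they did so. Their camera BH-adjusted p-values with GC and length, GC alone and the first form were 0.544, 0.390 and 0.477 for basal prostate, 0.759, 0.822 and 0.811 for neuroendocrine, 0.849, 0.822 and 0.477 for hypoxia, and 0.759, 0.648 and 0.617 for TGF-beta and YAP. For p53 targets they were 0.957 and 0.867 with GC and length and GC alone. Basal prostate also turned with fry (0.763), without F133V replicate 2 (0.897) and without wild-type replicate 1 (0.888), its p ranging from 0.833 to 0.897 over the fits that leave out a library. Hypoxia turned without F133V replicate 2 (0.897) alone of these fits, over which its p ranged from 0.338 to 0.897. The cause was not tested for these lists.

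With replicate number as a block, 9365 genes were called, 4619 higher and 4746 lower, and basal prostate turned direction (0.866). Replicate 1 of both genotypes deviated from the genotype means with a correlation of -0.027. The difference between the F133V replicates followed GC content (rho 0.77), and that between the wild-type replicates did not (rho -0.07). The correlation therefore cannot show whether the replicate numbers mark a shared culture or day. Depth of 35173245 reads or more per library limits mainly genes of low count, such as the markers of other cell types.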

Other observations

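The genes in these paragraphs were chosen after their values were seen, and the requirement on shuffles and the rank statistic for chromosome windows were added after the window medians were seen. Genes that rose in F133V cells included the thioredoxin inhibitor TXNIP (1.18 ± 0.085, GC-adjusted 1.39), the Notch target HES1 (1.35 ± 0.10, GC-adjusted 1.24), the transcription factor RUNX2 (1.27 ± 0.13, GC-adjusted 1.39), and the circadian factor DBP (1.53 ± 0.11, GC-adjusted 1.35), as log2 fold change ± SE by edgeR. The cell cycle inhibitor CDKN1C rose as well, at 7.13 ± 0.233 CPM in F133V cells and 2.41 ± 0.00688 CPM in wild-type cells (SD, n = 2 each). TXNIP was at 51.7 ± 6.0 CPM in F133V cells and 22.8 ± 1.23 CPM in wild-type cells (SD, n = 2 each). Low-level genes that rose included GDF15 (2.0 ± 0.32, GC-adjusted 1.69), BST2 (2.21 ± 0.49, GC-adjusted 1.94), CEACAM6 (1.95 ± 0.19, GC-adjusted 2.01) and the actin-bundling LCP1 (1.73 ± 0.15, GC-adjusted 1.86); GDF15 and BST2 stayed near 1 CPM or below in F133V cells. SELENOP (0.69 ± 0.13, GC-adjusted 1.39) had a larger value with GC adjustment than without.

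MKI67 (-0.83 ± 0.058, GC-adjusted -0.73) and TOP2A (-1.13 ± 0.074, GC-adjusted -0.56), both made mainly in dividing cells, fell as well. MKI67 was at 410.5 ± 27.4 CPM in F133V cells and 731 ± 9.89 CPM in wild-type cells (SD, n = 2 each). RAD50 (-1.34 ± 0.17, GC-adjusted -0.87) was low in all libraries, at 1.46 ± 0.296 CPM in F133V cells and 3.69 ± 0.185 CPM in wild-type cells. The largest falls after GC adjustment also included the pseudogene USP32P3 (-1.16 ± 0.088, GC-adjusted -1.33), the long noncoding RNA gene MIR22HG (-1.08 ± 0.091, GC-adjusted -1.14) and FAM86C1P (-0.78 ± 0.10, GC-adjusted -0.97), which the annotation used here gives as protein-coding. Reads of USP32P3 are less certainly its own. HNRNPM (-0.74 ± 0.059, GC-adjusted -0.93), a splicing factor, FJX1 (-0.56 ± 0.073, GC-adjusted -0.86) and NAV3 (-1.14 ± 0.08, GC-adjusted -0.88) fell too, and HNRNPM and FJX1 fell further after adjustment. DOCK10 fell as well, at 24.7 ± 3.57 CPM in F133V cells and 59.0 ± 3.32 CPM in wild-type cells (SD, n = 2 each), with a GC-adjusted log2 fold change of -0.87.

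A copy-number difference between the F133V and wild-type cells was examined as a hypothesis for neighbouring genes moving together, in 297 windows of 10 Mb with at least 10 tested genes. The largest median adjusted log2 fold change of a window was 0.357, on chromosome 8 from 110000001 to 120000000, and 3 windows exceeded 0.3, which by the first criterion would count for the hypothesis. In 1000 shuffles of genes over windows, 117 had a window as large, so a copy-number difference may be present but cannot be told apart from chance on that measure. By rank, chromosome 1 from 200000001 to 210000000 (104 genes, median 0.22, 51 higher and 6 lower) gave a z of 5.48, beyond the largest of 4.50 over the shuffles; the windows on either side had medians of 0.067 and 0.0098. Shuffling treats neighbouring genes as independent, which co-regulated neighbours are not, and DNA copy number was not analysed here. Differences spanning several windows were not tested. Every window of chromosome 15 from 60000001 to 110000000 had a median above 0 (0.083 to 0.34). So did every window of chromosome 8 from 1 to 50000000 (0.10 to 0.15). These runs were picked after the medians were seen. The window from 50000001 to 60000000 lay below 0 on chromosomes 15 and 8 (-0.046 and -0.048).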
